A study of Mus musculus with 6 samples.

How the data were processed

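Livers of 12-week-old male mice were compared by RNA-seq between 3 C57BL/6J wild-type (WT) animals and 3 animals of the same background that lack Zpbp2, the gene for zona pellucida binding protein 2 (Zpbp2 KO). Per the labels' protocols, 250 ng of total RNA from each liver went through poly(A) selection and a directional cDNA kit, and the libraries were read as pairs of 100 cycles on an Illumina HiSeq instrument. The labels name 3 livers of each genotype and 1 library per sample, so the spread within a group is a spread between animals.

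The deposited table holds counts, whole numbers per Ensembl gene ID and library, with no normalization. STAR, Picard and HTSeq are named for these counts per the submitters' processing notes, with the genome build mm9. Their versions and settings, the gene annotation behind the counts and the strand setting of the counting are not given in the sources used here. Reads of near-identical copies, such as class I histocompatibility genes, Hspa1a and Hspa1b or the Saa, Orm, Cyp4a and alpha globin genes, may have been split or dropped by the counting, and genes that overlap on opposite strands may share reads, so values of such genes are less certain. All 6 columns of the table were used, and each was matched to its sample by its title. Gene symbols came from the GENCODE M21 names for GRCm38 and, for IDs not listed there, from a RefSeq table, matched on Ensembl IDs. Of 37991 IDs, 32919 (86.6%) matched a symbol and 5072 did not. The unmatched IDs held 0.345% to 0.430% of a library's counts. Because the counts were made on mm9, no coordinates are given, and only chromosome names and the order of genes along a chromosome were taken from GENCODE M21.

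Total counts ran from 37904891 to 52955687 per library. A count of 0 in these libraries allows up to 3 counts, which is 0.0560 to 0.0786 on the counts-per-million scale (CPM). Such limits, and exact intervals on counts, cover counting error only, because PCR copies of a molecule were not told apart. Replicates of a group differed from each other by far more than sampling noise, with a chi-square of 19.9 to 102 per gene between pairs of the same group, so no library was taken for a copy of another.

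Changes between genotypes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 14686 genes, and libraries were scaled by TMM. The quasi-likelihood F-test compared Zpbp2 KO with WT, with no covariate, two-sided, and genes with a Benjamini-Hochberg adjusted p below 0.05 over all tested genes were called. CPM values use the TMM-scaled library sizes and are given as mean ± SD of 3 livers. Log2 fold changes are Zpbp2 KO over WT and are given ± SE, the SE being that implied by the test. For 38 gene lists written from textbook knowledge, camera (limma 3.58.1) with its preset correlation of 0.01 compared each list with all other tested genes on log2 CPM with a prior count of 2, over the 36 lists with at least 5 tested members, again with Benjamini-Hochberg adjustment. The same lists were tested with the correlation estimated per list, and with fry, which asks whether a list's genes move 1 way and does not compare them with other genes. A list's members were also adjusted over the list alone.

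The groups, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined, except where a later choice is stated. The rule named Zpbp2 and its called neighbours on the list of them, or, with none called, the 3 listed neighbours with the smallest p. It then took the 8 called genes with the largest rise and the 8 with the largest fall among those without overlap between the groups and with a mean log2 CPM of at least 0, or all such genes if fewer, leaving out clone and prediction names (0 were left out). From each list past the set test it took up to 2 called members per direction, or, with none called, the 2 members with the smallest p. Any other gene in the text was chosen after its values were seen.

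Alternatives were DESeq2 1.42.0 (Wald test), limma-voom, DESeq2's size factors or library totals in place of TMM, no filter on low counts, a filter of 20 counts in at least 3 libraries, the replicate number as a block, a robust fit, and each library left out in turn. Offsets that remove each library's trend with transcript length and GC content were added after seeing the data. Lengths and GC content came from GENCODE M21 transcripts and covered 97.0% of the tested genes.

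The tests were checked on counts simulated from the means and depths of this comparison over 14686 genes, 200 of them changed. The edgeR test recovered 7.81% of genes changed 1.5-fold, 45.7% of those changed 2-fold and 86.4% of those changed 4-fold, with 11 false calls. DESeq2 recovered 21.9%, 67.1% and 87.9%, with 31 false calls, and limma-voom 4.69%, 45.7% and 86.4%, with 10. With the antigen presentation list raised by 0.5 on the log2 scale, camera found that list (adjusted p = 2.13e-15) and 0 of the other lists. That result holds for the simulated counts and does not show how camera behaves in the livers. There the correlation estimated per list reached 0.938, and groupings that mixed the genotypes gave up to 16 lists past camera.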

Results

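The transcriptomes of 6 mouse livers were measured, 3 from WT and 3 from Zpbp2 KO males, to ask which liver transcripts differ when Zpbp2 is missing. Zpbp2 encodes a sperm protein that binds the egg coat, and it lies next to Ormdl3 and the gasdermin genes in a region tied to asthma in people. The series title links the knockout to a milder asthma-like state and to changed lipid metabolism. Total counts were 51596616, 52955687 and 37904891 in WT replicates 1 to 3 and 47821653, 48101737 and 51328826 in Zpbp2 KO replicates 1 to 3. Between 19127 and 19777 genes had a count in a library. Albumin (Alb) was the most abundant transcript in every library, with 6.68% to 7.83% of counts. Transcripts of the mitochondrial genome took 4.84% to 5.81%, the highest share being that of Zpbp2 KO replicate 2.

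Zpbp2 itself (ENSMUSG00000017195, chromosome 11) was barely transcribed in WT liver and gave no read in the knockout livers. WT replicates 1, 2 and 3 held 4, 13 and 7 counts, a mean of 0.168 ± 0.0844 CPM (SD, n = 3), and each Zpbp2 KO library held 0, at least 8.08-fold lower when the limit of 3 counts is set over the whole group. The libraries without a read were those labelled Zpbp2 KO, and all 3 WT libraries held reads. An exact binomial test on the counts gave p = 5.27e-08, which compares these libraries and not the genotypes. Across animals the two-sided exact permutation test gave p = 0.1, the smallest value that 3 livers against 3 allow. The gene was below the expression filter. Which part of the gene the allele removes is not given in the sources used here.

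Sik1 and Nr4a1 fell in Zpbp2 KO livers, and they were the only genes called among 14686 by edgeR's quasi-likelihood test. Sik1 (ENSMUSG00000024042, chromosome 17) encodes salt-inducible kinase 1, a cAMP-induced kinase that restrains CREB-driven transcription. It went from 51.5 ± 3.77 CPM in WT to 12.0 ± 1.27 CPM in Zpbp2 KO livers (SD, n = 3), a log2 fold change of -2.10 ± 0.118, with an adjusted p of 0.000993 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Nr4a1 (ENSMUSG00000023034, chromosome 15) encodes an orphan nuclear receptor of the immediate early class. It went from 24.9 ± 8.66 to 1.51 ± 0.248 CPM, a log2 fold change of -4.04 ± 0.302, with an adjusted p of 0.00499 by the same test and adjustment. Both were lower in each of the 3 knockout livers than in any WT liver. The Nr4a1 call was lost with limma-voom (adjusted p = 0.0523) and without Zpbp2 KO replicate 3 (adjusted p = 0.0923 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

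**Figure D1:**
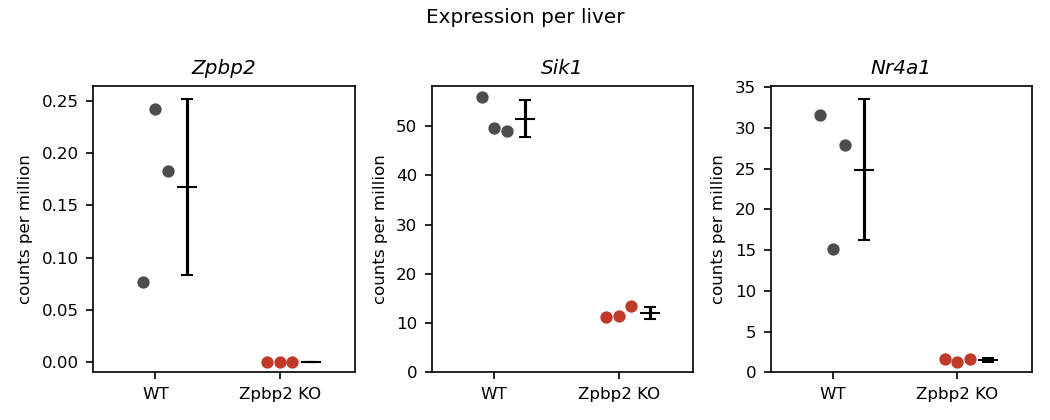
Expression (CPM) of Zpbp2, Sik1 and Nr4a1 in each of the 6 livers, WT in grey and Zpbp2 KO in red, with the mean and SD of 3 livers beside the points. Zpbp2 had 0 counts in all 3 knockout libraries, and Sik1 averaged 51.5 CPM in WT and 12.0 CPM in Zpbp2 KO livers.

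No gene was called higher by edgeR (0 genes, with 420 higher and 430 lower at an unadjusted p below 0.05). Chance alone would give 734.3 in all on average, but groupings of the livers that mix the genotypes gave 235 to 1753. No excess over chance is thus shown. The balance of the 2 directions depends on the scaling, with 389 higher and 481 lower under DESeq2's size factors and 335 higher and 519 lower under library totals. DESeq2 called 25 higher and 49 lower, both of the edgeR calls among them, and limma-voom called 0 higher and 2 lower, Sik1 and C130046K22Rik on chromosome 11. In simulated counts DESeq2 made 31 false calls and edgeR 11, so calls by DESeq2 alone, here and below, are less certain. Of the tested genes, 1699 (11.6%) showed no overlap between the groups, against 10% by chance. All other genes below are therefore given with their values, not as called changes.

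Immediate early and stress-activated genes, which cells transcribe within minutes of a stimulus, lay lower in the knockout livers. Of 24 tested members 18 were below 0, with a median log2 fold change of -0.34, and 1 member, Nr4a1, was called lower over all genes by edgeR and 4, Nr4a1, Ccn1, Fos and Atf3, by DESeq2. Adjusted over the list alone, 6 members passed as lower and 1 as higher. Among the lower ones were Fos (-1.49 ± 0.325, from 2.20 ± 0.761 to 0.781 ± 0.156 CPM), Ccn1 (-1.26 ± 0.201) and Jun (-0.98 ± 0.299). Zfp36, which encodes a protein that destabilises mRNA, was the member in the other direction (0.48 ± 0.148). The list passed camera (adjusted p = 1.75e-05), but not with the correlation estimated from the data (adjusted p = 0.455 with an estimated correlation). Heat shock proteins, which refold damaged proteins, had a median of -0.10 with 12 of 18 members below 0 and passed camera (adjusted p = 0.0189), though not with the correlation estimated (adjusted p = 0.752 with an estimated correlation). The call was also lost without WT replicate 3 (adjusted p = 0.292) and without Zpbp2 KO replicate 3 (adjusted p = 0.437). Its lowest p-values were those of the inducible Hsp70 genes Hspa1a (-1.76 ± 0.390) and Hspa1b (-1.11 ± 0.319), of which Hspa1a passed adjusted over the list alone, and DESeq2 called both over all genes. The unfolded protein and integrated stress response list had a median of 0.06 and did not pass camera (adjusted p = 0.924). Adjusted over the list alone, 1 of its 28 members passed as higher and 2 as lower, namely Chac1 (1.73 ± 0.348), Sesn2 (-0.82 ± 0.169) and Atf3 (-1.12 ± 0.248), the last also on the immediate early list, and DESeq2 called the same 3 over all genes.

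Among the lists of lipid metabolism, which the series title names, those for cholesterol synthesis and fatty acid oxidation showed small shifts. These passed camera only with its preset correlation. On the lipid lists edgeR called 0 genes, while DESeq2 called Pdk4, Lpin1, Lipg and G0s2. Genes of cholesterol synthesis and SREBP2 targets had a median log2 fold change of 0.21, with 19 of 24 tested members above 0. Fdps, which makes farnesyl diphosphate, stood at 254 ± 34.3 CPM in WT and 350 ± 36.0 CPM in Zpbp2 KO livers (0.46 ± 0.130), and Fdft1, squalene synthase, at 135 ± 10.3 and 163 ± 8.63 CPM (0.27 ± 0.0970). Fatty acid oxidation, ketogenesis and PPARa target genes went the other way, with a median of -0.17 and 31 of 37 members below 0. Pdk4, the kinase that shuts off pyruvate dehydrogenase in fasting, stood at 16.0 ± 4.81 and 5.54 ± 1.32 CPM (-1.53 ± 0.253), and the omega-hydroxylase gene Cyp4a31 at 6.91 ± 2.24 and 3.69 ± 0.504 CPM (-0.90 ± 0.255). Pdk4 was the single member of either list to pass adjusted over the list alone, 1 lower in fatty acid oxidation and 0 in cholesterol synthesis. DESeq2 called Pdk4 (adjusted p = 2.28e-06), edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes did not (adjusted p = 0.287). Both lists passed camera (adjusted p = 0.000686 for cholesterol synthesis and 5.11e-05 for fatty acid oxidation) and neither did once the correlation was estimated (cholesterol synthesis adjusted p = 0.691 with an estimated correlation, fatty acid oxidation adjusted p = 0.752 with an estimated correlation). Leaving out Zpbp2 KO replicate 3 ended the first call (adjusted p = 0.262) and leaving out WT replicate 1 the second (adjusted p = 0.0688).

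The other lipid lists did not pass camera. Fatty acid and triglyceride synthesis had a median of 0.11, with 18 of 27 members above 0 and 3 at an unadjusted p below 0.05, and was nearest to the threshold (adjusted p = 0.0574). Its lowest p-value was that of Lpin1, a phosphatidate phosphatase, at 60.6 ± 23.6 CPM in WT and 141 ± 50.6 CPM in Zpbp2 KO livers (1.22 ± 0.330), with overlap between the groups and an adjusted p of 0.0227 by DESeq2. Sphingolipid metabolism, the pathway that ORMDL proteins restrain, had a median of -0.02, and 0 of its 36 tested members reached an unadjusted p below 0.05 by edgeR (camera adjusted p = 0.924). Medians were 0.08 for lipoprotein assembly and lipid transport (30 genes, adjusted p = 0.411), -0.07 for lipid droplets and lipolysis (20 genes, 0.133), -0.05 for phospholipid remodelling (23 genes, 0.489) and 0.01 for bile acid synthesis and transport (22 genes, 0.924). After removal of the length and GC trend, an alternative chosen after seeing the data, fatty acid and triglyceride synthesis (0.0199) and lipid droplets and lipolysis (0.0201) passed camera. By DESeq2, Lipg, endothelial lipase (-1.30 ± 0.398), and G0s2, an inhibitor of lipolysis (-1.26 ± 0.347), were called, which edgeR did not call. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 56.3 ± 16.0 CPM in WT and 110 ± 58.9 CPM in Zpbp2 KO livers (0.97 ± 0.359), with overlap between the groups.

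**Figure D2:**
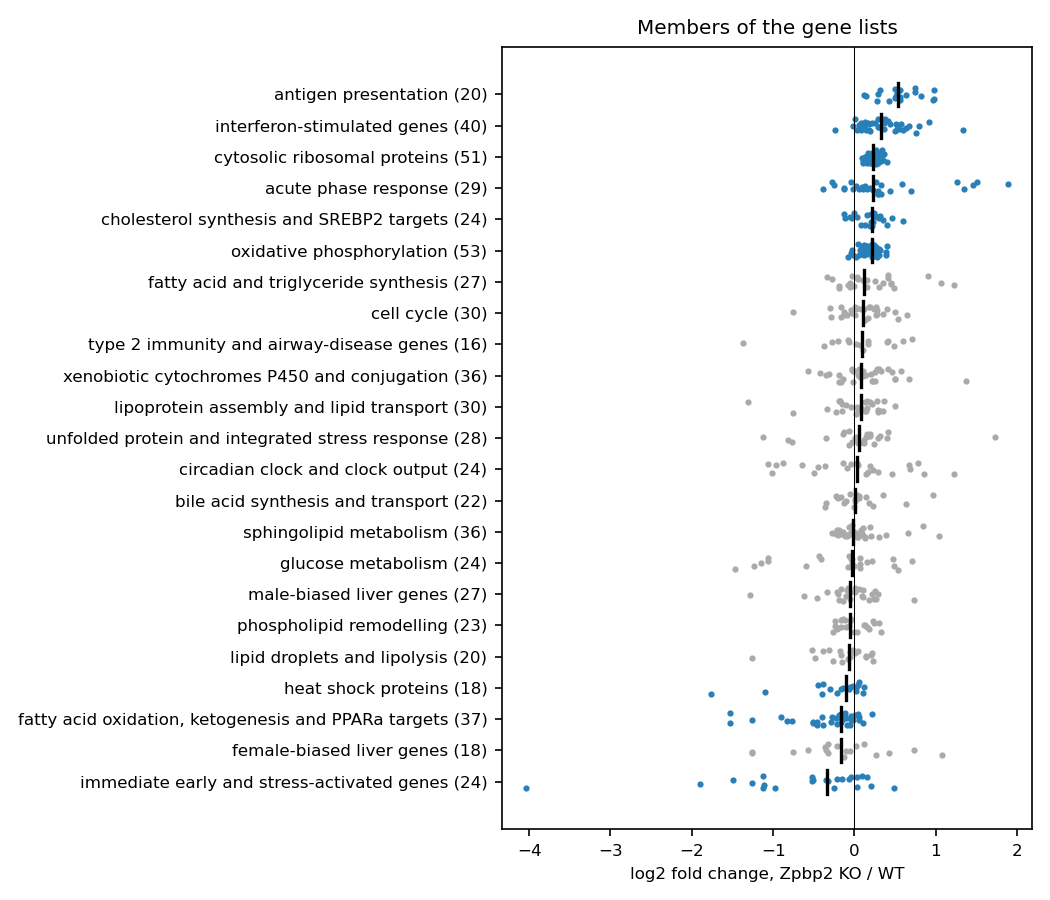
Log2 fold changes (Zpbp2 KO over WT) of the tested members of the lists for metabolism, stress and immunity, 1 point per gene, the black bar being the list's median and the number of tested genes in brackets. Blue marks lists that passed camera with its preset correlation and grey those that did not. All 20 antigen presentation genes lie above 0, and Nr4a1 at -4.04 is the point farthest to the left.

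Of the remaining metabolic lists, glucose metabolism held 6 genes lower and 2 higher at an unadjusted p below 0.05, with a median of -0.03 over 24 genes (camera adjusted p = 0.167). Ppp1r3c, a subunit that directs phosphatase to glycogen, passed adjusted over the list alone (-1.06 ± 0.180), and the insulin-repressed genes Irs2 (-1.24 ± 0.342), Igfbp1 (-1.15 ± 0.330) and G6pc (-1.07 ± 0.450) had values below 0. On this list DESeq2 called 3 genes lower (Ppp1r3c, Irs2 and Igfbp1) and edgeR 0. Clock and clock output genes had a median of 0.04 (24 genes, adjusted p = 0.611), and xenobiotic cytochromes P450 and conjugation enzymes 0.09 (36 genes, adjusted p = 0.0574, and 0.0262 with the replicate block). Male-biased liver genes had a median of -0.05 (27 genes, adjusted p = 0.924), with Mup20, a urinary pheromone protein, the member that passed adjusted over the list alone (-0.61 ± 0.111) and the 1 that DESeq2 called. Female-biased genes had -0.17 (18 genes, adjusted p = 0.743) and cell cycle genes 0.10 (30 genes, adjusted p = 0.924).

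Antigen presentation, interferon-stimulated and acute phase genes lay higher in the knockout livers as groups, with 0 members called by edgeR. Not all genes of immunity did. Type 2 immunity and airway-disease genes had a median of 0.09 and did not pass camera, and the inflammatory cytokine gene Il1b was lower (-2.23 ± 0.270). Of the 3 higher lists, members called by DESeq2 follow. DESeq2 called 3 antigen presentation genes (H2-T23, H2-Q7 and H2-D1), 5 acute phase genes (Saa1, Saa2, Orm2, Orm3 and Lcn2) and 0 interferon-stimulated genes, all higher. All 20 tested antigen presentation genes were above 0, with a median of 0.54, and 11 passed adjusted over the list alone. The class I molecules H2-T23 (186 ± 14.4 and 273 ± 13.1 CPM, 0.56 ± 0.0971) and H2-Q7 (56.9 ± 2.54 and 83.6 ± 10.4 CPM, 0.56 ± 0.114) had the smallest p-values. Interferon-stimulated genes had a median of 0.32, with 38 of 40 above 0 and 7 past the test adjusted over the list alone, led by the nucleic acid sensor Zbp1 (0.60 ± 0.137) and Rtp4 (0.54 ± 0.132). Acute phase genes, which the liver secretes in inflammation, had a median of 0.23, with 22 of 29 above 0 and 5 past the test adjusted over the list alone. Serum amyloid A gene Saa1 stood at 23.4 ± 6.31 and 59.2 ± 8.78 CPM (1.34 ± 0.208) and the orosomucoid Orm2 at 3.13 ± 0.779 and 8.56 ± 1.32 CPM (1.45 ± 0.228). The lists passed camera (adjusted p = 9.16e-13 for antigen presentation, 3.82e-10 for interferon and 2.57e-05 for acute phase), and did so with each library left out in turn, but not when the correlation was estimated (for all 3, adjusted p = 0.455 with an estimated correlation).

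Markers of leukocytes were measured beside them. T and NK cell markers had a median of 0.30 (18 of 20 above 0), B and plasma cell markers 0.40 (13 of 17 above 0), and Kupffer cell and macrophage markers 0.12 (18 of 20 above 0). T cell receptor gene Trbc1 (0.164 ± 0.0913 and 0.384 ± 0.187 CPM, 1.21 ± 0.535), the T cell kinase gene Lck (0.51 ± 0.291), and the B cell genes Pax5 (0.86 ± 0.342) and Fcer2a (0.57 ± 0.278) had the smallest p-values. The first 2 lists passed camera (adjusted p = 0.00659 for T and NK cells and 0.0148 for B cells), but for both adjusted p = 0.752 with an estimated correlation, 0 members passed adjusted over the list alone, and at an unadjusted p below 0.05 edgeR had 0 T and NK and 1 B cell member. Their calls were lost without WT replicate 2 (0.249 for both), without Zpbp2 KO replicate 1 (0.0835 for T and NK, 0.184 for B cells) and without Zpbp2 KO replicate 3 (0.285 and 0.222). Kupffer cell markers did not pass (adjusted p = 0.675). Erythroid markers had the highest median, 0.77 over 9 genes, with Hbb-bs at 29.8 ± 14.7 and 73.0 ± 42.7 CPM, and did not pass (adjusted p = 0.0525), but did with DESeq2's size factors (adjusted p = 0.0481) and with the replicate block (adjusted p = 0.0411).

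Other cell markers did not pass camera either. Medians were 0.10 for hepatocyte markers (17 genes, adjusted p = 0.0539), 0.01 for periportal (15 genes, 0.924) and 0.15 for pericentral hepatocyte genes (17 genes, 0.173), -0.03 for endothelial cells (19 genes, 0.411), 0.04 for stellate cells and fibroblasts (19 genes, 0.726), 0.07 for cholangiocytes (13 genes, 0.924) and 0.27 for platelets and megakaryocytes (5 genes, 0.0539, and 0.0460 with the replicate block). Markers of adipose tissue, pancreas, muscle and gut had a median of 0.51 over 6 genes (0.388), and type 2 immunity and airway-disease genes 0.09 over 16 genes (0.924). Neutrophil and mast cell markers, with 4 tested members, and sperm and testis genes, with 0 tested members and 119 counts over all libraries, were too few to test.

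Genes for ribosomal proteins and for oxidative phosphorylation lay slightly higher as groups, by an amount that shrank with a correction for transcript length and GC content. All 51 tested cytosolic ribosomal protein genes were above 0 (median 0.23), for example Rpl36 (0.40 ± 0.145) and Rpl3 (0.25 ± 0.0930), and 49 of 53 oxidative phosphorylation genes were (median 0.21), for example Ndufa2 (0.39 ± 0.138) and Sdhb (0.24 ± 0.0886). Adjusted over the list alone, 0 members of either list passed, with 8 and 5 higher at an unadjusted p below 0.05 by edgeR. Camera called both (adjusted p = 1.38e-11 and 2.18e-08), but for each adjusted p = 0.752 with an estimated correlation. In Zpbp2 KO replicate 3, Rpl36 (106 CPM, WT 95.8 to 107) and Ndufa2 (56.7 CPM, WT 50.6 to 56.0) stood near WT. Rpl3 (229 CPM, WT 203 to 209) and Sdhb (189 CPM, WT 168 to 175) stood above WT in that liver. Without that library the camera adjusted p fell to 2.90e-21 for ribosomal proteins and 5.04e-13 for oxidative phosphorylation. With the length and GC trend removed, the median was 0.10 for ribosomal proteins (adjusted p = 1.73e-05) and 0.06 for oxidative phosphorylation (adjusted p = 0.0118), and Rpl36, Rpl3, Ndufa2 and Sdhb stood at 0.20, 0.17, 0.18 and 0.11. Transcripts of the mitochondrial genome took 4.97 ± 0.0984% of counts in WT and 5.17 ± 0.559% in Zpbp2 KO livers.

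The list of neighbours of Zpbp2 on chromosome 11, written from textbook knowledge and not complete, had 26 tested members and held 0 genes called by edgeR and 0 by DESeq2, with 2 higher and 0 lower at an unadjusted p below 0.05 by edgeR. The smallest p-values on the list were those of Rapgefl1 (0.529 ± 0.138 and 1.09 ± 0.110 CPM, 1.06 ± 0.275), Mien1 (34.4 ± 3.89 and 53.4 ± 11.3 CPM, 0.64 ± 0.168) and the replication gene Cdc6 (0.294 ± 0.0283 and 0.194 ± 0.0585 CPM, -0.59 ± 0.355). Adjusted over the list alone, 0 passed. Ormdl3, the regulator of sphingolipid synthesis next to Zpbp2, was looked up after the values were seen and stood at 92.4 ± 12.1 CPM in WT and 93.8 ± 11.4 CPM in Zpbp2 KO livers (0.02 ± 0.133). Tested genes that the list leaves out include Gm12352 (0.89 ± 0.269), Gm12359 (-0.86 ± 0.289) and Stac2 (2.39 ± 0.438), which lie 3, 8 and 12 tested genes from Zpbp2, had an unadjusted p below 0.05 by edgeR and were called by neither tool. As a list the neighbours had a median of 0.02 and did not pass camera (adjusted p = 0.895).

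**Figure D3:**
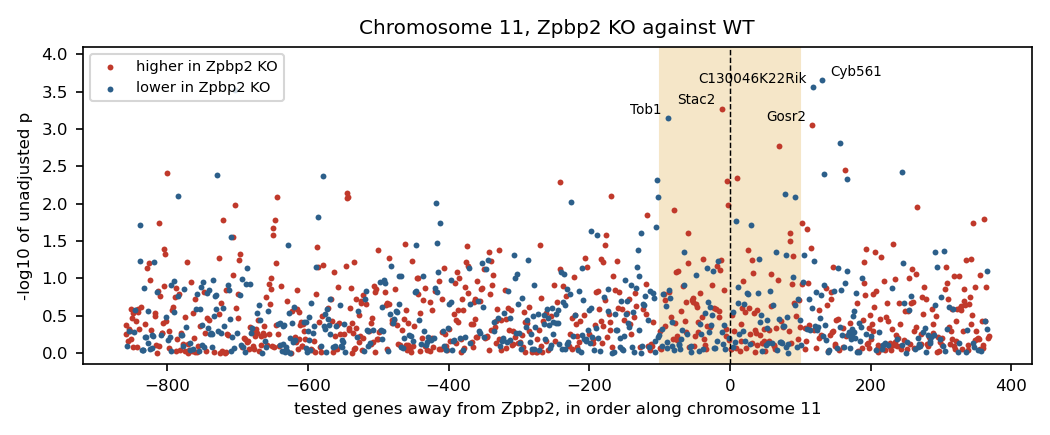
The -log10 of the unadjusted p of each tested gene on chromosome 11 against its distance from Zpbp2, counted in tested genes along the chromosome, with genes higher in Zpbp2 KO livers in red and lower ones in blue. The shaded band marks the 100 genes on each side of Zpbp2, of which 10 higher and 8 lower had an unadjusted p below 0.05.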

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

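The offsets for transcript length and GC content, and all alternative settings for genes near Zpbp2, were chosen after the result was seen, and the others were planned. The count of higher genes, 0 by edgeR, was 25 with DESeq2 and 3 without a filter on low counts, and 0 to 1 with a library left out. The count of lower genes, 2 by edgeR, was 49 with DESeq2 and 9 without a filter, and 2 to 4 with a library left out. The highest counts came without Zpbp2 KO replicate 1 for higher genes and without Zpbp2 KO replicate 2 for lower genes. Both edgeR calls were among those of DESeq2, of the unfiltered fit and of the fits with other scalings, while limma-voom and the fit without Zpbp2 KO replicate 3 shared 1 of them. Without that library the genes at an unadjusted p below 0.05 went from 850 to 1041 higher and 951 lower. Sik1 kept its call under each alternative, with leave-one-out adjusted p from 0.00356 to 0.0191 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. No scaling moved the median log2 fold change of all genes by more than 0.1, the largest shift being -0.0332 with library totals. Of 373 alternative values of the 25 named genes, 362 stayed on their side of the threshold, 2 lost a call (both Nr4a1), 9 gained one and 0 reversed. WT mean CPM of Zpbp2 ran from 0.130 to 0.213 with a WT library left out.

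The 11 lists past camera with its preset correlation fell to 0 with an estimated correlation and to 0 with fry after adjustment over the lists, and ranged from 10 to 17 with a library left out, the 17 being without Zpbp2 KO replicate 2. Of 132 alternative values of these lists, 100 stayed past the threshold and 32 did not, 0 with the opposite direction. Lists that had not passed could do so with a library left out, such as Kupffer cell and macrophage markers, whose lowest leave-one-out adjusted p was 1.08e-09. The causes of these differences were not tested. With the replicate block, edgeR called 0 genes higher and 2 lower and camera 14 lists, and the block changed no call of a named gene. Correlations of same-numbered livers were 0.107, 0.198 and -0.242 over the 2000 most variable genes, and not every liver correlated best with its own number, so the numbers were not taken as pairs. In simulated data the edgeR test found 7.81% of 1.5-fold changes, so shifts of the size seen in the lists were mostly out of reach gene by gene.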

Other observations

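The sets of feeding, clock and CREB target genes, the comparison with leukocyte markers, the check on class I paralogs, the direction of genes near Zpbp2, the other settings for genes near Zpbp2, the splits for feeding genes and the share at an unadjusted p below 0.01 per chromosome were tests chosen after the result was seen, and the genes named in this part were chosen after their values were seen.

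DESeq2 called 74 genes, most of which edgeR did not call, and 4 of them on no list above are given here. Slc25a25, a mitochondrial carrier of ATP-Mg and phosphate, stood at 420 ± 40.7 CPM in WT and 127 ± 34.8 CPM in Zpbp2 KO livers, a log2 fold change of -1.72 ± 0.201 (SD and SE, 3 livers per group). Csad, which makes the taurine precursor hypotaurine, stood at 572 ± 137 and 269 ± 54.2 CPM (-1.09 ± 0.204), and Alas1, the rate-limiting enzyme of heme synthesis, at 171 ± 63.5 and 444 ± 137 CPM (1.38 ± 0.303). The inflammatory cytokine gene Il1b stood at 5.97 ± 1.11 and 1.27 ± 0.406 CPM (-2.23 ± 0.270). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.105 for Slc25a25, 0.376 for Csad, 0.475 for Alas1 and 0.106 for Il1b. Cela2a, a pancreatic elastase gene, was at 29.8 CPM in Zpbp2 KO replicate 1 and at 0.553 to 0.789 CPM in the other 5 livers.

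Most of a chosen set of genes known to follow feeding, which is not complete, had values on the fed side. The exceptions were Me1, which feeding raises (-0.28 ± 0.178), and Ppargc1a, which fasting raises (0.49 ± 0.364). Of 13 genes that feeding raises, 12 were above 0, among them Thrsp (0.90 ± 0.436) and Fasn (0.45 ± 0.271), and of 13 that fasting raises, 12 were below 0, among them Irs2 (-1.24 ± 0.342), G6pc (-1.07 ± 0.450) and Angptl4 (-0.51 ± 0.271). All 26 also belong to the lists fixed earlier, whose directions had been seen, so they are no independent evidence. None was called by edgeR (0 genes, 6 at an unadjusted p below 0.05), and DESeq2 called 1 of them, Irs2. The splits of 6 livers are too few for a share under 0.05, so chance cannot be judged. The signed median was 0.41 for the real split, the only 1 of 10 to reach it, and 0.32 for the highest other.

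The lower immediate early genes, with Sik1 and Nr4a1, could reflect how the livers were collected rather than the loss of Zpbp2. Length and GC content are argued against, since after their removal Sik1 stayed at -2.07 ± 0.104 (adjusted p = 0.000654 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Feeding state stays open. The signed median of feeding and fasting genes was 0.41 (95% bootstrap interval 0.30 to 0.48, fry adjusted p = 0.0332 over this set and the CREB set alone). Over the 36 lists, adjusted together, 0 passed fry. Here and below, bootstrap intervals resampled genes and not livers, so they do not measure the spread between animals. The feeding and fasting genes had been seen through their lists, so they add no independent support, and a genotype effect would look alike. Time of collection stays open too, since the median absolute log2 fold change of 13 clock genes, 0.50 (0.29 to 0.85), lies above 0 even with no difference and decides nothing, and clock genes varied within groups (Per1 16.4 ± 14.5 CPM in WT). Lower cAMP and CREB signalling, a biological candidate, is undecided. The median was -0.12 (-0.42 to 0.07, fry adjusted p = 0.0332 over the same sets) over 18 other targets, 3 of them on the immediate early list. Without those 3 it was -0.09. Pck1, Tat and Ppargc1a were also among the feeding and fasting genes, so they too had been seen through their lists. Per1 and Nfil3 were also among the clock genes, so these sets overlap. The immediate early list had an absolute median of 0.34 for the real split and 0.30 for the highest other of 10 splits. These splits, compared after the result was seen, are too few to judge chance.

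Higher antigen presentation may come from more leukocytes or from a change within liver cells, among other causes. H2-T23, H2-Q7 and H2-D1, which DESeq2 called, all lie on chromosome 17, so the list's members are not all on separate chromosomes. A cause tied to that chromosome was not tested. Of its genes 6.42% had an unadjusted p below 0.05 (odds ratio 1.13, Fisher's exact p = 0.454, 0.648 adjusted over 20 chromosomes). Reads moving from 1 counted class I copy to another are argued against, since 14 of 15 class I heavy chain genes gained 849 CPM while 1 lost 0.373 CPM, 0.0439% of the gain. Reads that the counting may have dropped are not covered, because a gain from them would leave no loss in any counted copy. The summed counts of these 15 genes had a smaller log2 fold change, 0.26 ± 0.103 (unadjusted p = 0.0332 by edgeR's quasi-likelihood test). That sum is weighted by abundance, and the most abundant of them, H2-Q10, changed little (2192 ± 211 and 2417 ± 257 CPM, 0.14 ± 0.122). A trend with length or GC content is also argued against, as its removal left the list's median at 0.52 (0.38 to 0.61, camera adjusted p = 2.34e-12). Leukocytes stay open: 57 markers, 20 of them of resident Kupffer cells, 28 at 1 CPM or more in WT liver and 1 shared with another list, had a median of 0.24 against 0.50 for 13 genes of the class I pathway, a difference of -0.26 (-0.34 to 0.00), while 7 class II genes, typical of antigen-presenting cells, had 0.82. Among abundant markers Clec4f stood at 89.2 ± 8.48 and 101 ± 45.9 CPM and Cd5l at 80.5 ± 22.1 and 97.9 ± 52.0 CPM. The list's median of 0.54 stands against 0.36 for the highest other of 10 splits (1 as large, the real split), which are too few to judge chance. Some of the other splits passed camera on this list too, with an adjusted p as low as 8.74e-06, against 9.16e-13 for the real split.

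DNA of another strain kept beside the targeted gene could make genes around Zpbp2 differ more often, and the test of this passed in some fits and not in others. At an unadjusted p below 0.05 were 18 of the 200 nearest tested genes (9%) and 5.65% of 13017 genes on other chromosomes, an odds ratio of 1.65 (0.952 to 2.71, Fisher's exact p = 0.0623). It was 2.32 with DESeq2 (Fisher's exact p = 0.00253), 1.98 without a filter (0.00665), 1.89 with the replicate block (0.0205), and 1.53 to 1.73 in the 6 other fits of all libraries (0.0504 to 0.123), and with a library left out it ran from 1.18 without Zpbp2 KO replicate 3 (0.404) and 1.35 without Zpbp2 KO replicate 2 (0.233) to 2.13 without Zpbp2 KO replicate 1 (0.00674), the fits without WT replicates 1, 2 and 3 lying between, at 1.72 (0.0356), 1.87 (0.0394) and 1.99 (0.0212). With DESeq2 and without a filter, the near genes stayed at 200 but those on other chromosomes rose to 19410 and 19460. Of these, 3.85% and 5.31% had an unadjusted p below 0.05. They include genes below the expression filter, so both ratios compare unlike gene sets. Kept DNA and its poorer alignment both stay open, as 44.4% of the 18 genes were lower (exact 95% interval 21.5% to 69.2%), where 68.6% would be if all of the excess were lower. The highest other of 10 splits had an odds ratio of 2.01, and 3 of the 10, the real split included, had at least 1.65, which are too few to judge chance.

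Along chromosome 11, genes at an unadjusted p below 0.05 made up 7% and 11% of the nearest 100 on either side of Zpbp2, and 11% and 12% of the next 100 on either side. Over the whole chromosome the share was 7.01% (odds ratio 1.26, Fisher's exact p = 0.0544, 0.218 adjusted over 20 chromosomes). At an unadjusted p below 0.01 it was 30 of 1227 genes (2.44%), against 1.22% on other chromosomes (Fisher's exact p = 0.000968, 0.0194 adjusted over 20 chromosomes). Other splits of the livers gave chromosome 11 larger ratios on few genes, with 0.489% against 0.141% and 0.407% against 0.163%. C130046K22Rik, 118 tested genes from Zpbp2, had 13, 35 and 23 counts in WT and 0 in each knockout library, and was called by DESeq2 (adjusted p = 0.000187) and limma-voom (adjusted p = 0.0355) but not by edgeR (adjusted p = 0.287). Cyb561, 131 genes away, stood at 7.69 ± 1.98 and 1.56 ± 0.825 CPM (-2.29 ± 0.369) and was called by DESeq2 alone (adjusted p = 6.08e-08). Stac2, 12 genes away and called by none of these tools, had 5, 4 and 5 counts in WT and 30, 14 and 33 in Zpbp2 KO libraries.

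With 10 splits of the livers the share cannot fall under 0.05. The real split gave 2 called genes and the highest other also 2 (2 of the 10 splits, the real one included, had as many), and 11 lists past camera against 16 for the highest other (5 of the 10 had as many or more, the real one included). Genes at an unadjusted p below 0.05 numbered 850 in the real split and 1753 when WT replicate 1 and Zpbp2 KO replicates 1 and 3 were set against the others. They numbered 1487 with WT replicates 1 and 2 and Zpbp2 KO replicate 3 set apart. With WT replicate 1 and Zpbp2 KO replicates 1 and 2 set apart they numbered 1031. The remaining mixed groupings gave 235 to 620. Several groupings that mix the genotypes thus gave more such genes than the genotype did. What those groupings reflect was not tested.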
